A study of Ambystoma mexicanum with 4 samples.

How the data were processed

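Single cells of adult female axolotls were profiled with 10x Chromium droplets, per the labels. The 4 libraries are blood leukocytes, blood leukocytes with presumptive peritoneal macrophages, and amputated limb tissue collected 1 day and 6 days after amputation, with 1 library each. The deposited matrices hold raw UMI counts per transcript contig and cell barcode, written by Cell Ranger 3.0.2 per the file headers and already filtered to called cells. Version 2.1.1 is also named in the submitters' processing notes, and its role is not given in the sources used here. The reference, deposited as a gene table, comes from an earlier published transcript assembly per the series text. All 91648 contigs start at position 1, so that no genome coordinates are given, and the median contig length is 696 bases.

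Of the contigs, 36348 carry a gene symbol (16033 distinct symbols) and 55300 do not. Features were summed by symbol; those without a symbol, with 6.45% to 9.55% of UMIs per library, counted toward totals and the clustering but are reported only where stated. Symbols are those of the files, and a symbol can join several contigs, such as 4 for MMP8 and 2 for IL8. The matrices hold 7889 barcodes for blood, 4988 with peritoneal cells (the series text states 4998), 8272 for day 1 and 9906 for day 6. Total UMIs per library were 49983428, 65025429, 41324178 and 58266193. Free RNA was read from cells, since barcodes without cells are not used here.

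Barcodes with fewer than 200 detected genes were left out (27, 15, 30 and 169 per library), as were doublets called by Scrublet as run in scanpy 1.11.5 (123, 148, 4 and 1). The very few calls in the limb led to an added alternative that leaves out the highest doublet scores. Both libraries of a tissue were clustered together: counts scaled to 10000 per cell and log-transformed, 2000 variable features, 30 principal components, 15 exact nearest neighbours (scikit-learn 1.9.0), edges weighted by shared neighbours, and Leiden clustering at resolution 1 (igraph 0.11.9). No batch correction was applied, so a class can lie in different clusters in the 2 libraries, and these clusters are named beside the values. Random seeds were fixed.

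Clusters were named from 28 marker lists fixed before the data were examined, with basal and suprabasal epidermis joined. A marker counted as raised at 20 CPM or more and at least 2-fold over the median cluster, and the class with the highest mean over its 6 top markers was taken where at least 3 markers were raised. After the data were seen, a stricter rule was added. Leading genes were read from a pair of lists: the 10 with the largest fold over all other cells, and the 10 with the largest fold over the cells of clusters that best match another class. A cluster stayed unnamed when another class had more markers than its own on either list, or when its own class had none on the latter. It also stayed unnamed when its median UMI count was under the library median divided by 3 and the former list held no own marker, whatever the latter held. Limb clusters 3, 6, 9, 20 and 23 and blood clusters 14 and 19 have no own marker on the former list and are named from the latter. Left unnamed for too few markers were the clusters led by IGJ or CLEC17A and by GZMB; by the added rule, the LYZ-led cluster of blood, the low-UMI clusters and limb clusters 22 and 26. Names are therefore written as likenesses to a class. Shares of kept cells have exact 95% binomial intervals.

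Within each class of at least 50 cells in both libraries, UMIs were summed over cells and expressed as CPM, counts scaled to a common class total. Log2 ratios have exact conditional 95% intervals, which cover counting error alone. A count of 0 was set to a floor of 3 counts and then gives a bound. Genes were named by a rule fixed before the data were examined: at least 100 summed UMIs, an interval wholly beyond 2-fold, and the 5 largest ratios per direction (12 for limb erythrocyte-like and macrophage-like cells and for all cells, with their counterparts). Ratios are printed for a part of the named genes, and symbols that are clone or database numbers are left out. Values of some single genes, among them genes that met this rule, are not reported here; the list medians and counts include all measured members. The 20 gene lists were fixed before the data were examined as well. A list's median covers members with at least 20 summed counts, and its percentile is among 10000 random lists matched on mean expression in 20 bins. The lists cover inflammatory cytokines and regulators, immediate early genes, heat shock proteins, S phase, G2 and mitosis, matrix proteases and inhibitors, collagens and matrix, limb patterning and blastema, glycolysis, and oxidative phosphorylation. The others are MHC class II antigen presentation, interferon-stimulated genes, complement, lysosome and phagocytosis, iron and haem handling, lipid handling, secreted growth factors, wound keratinocyte, oxidative burst and redox, and cytoplasmic ribosomal proteins. Cycling cells were to be those with at least 2 UMIs of the G2 and mitosis list after thinning to 2000 UMIs, with shallower cells left out.

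Free RNA was estimated after the data were seen. Its profile was taken as the sum over all kept cells of a library, and its amount in a class as the haemoglobin share of the class divided by that of the library. For erythrocyte-like cells the amount came from macrophage markers, so that these markers are no evidence there. An observed CPM was divided by the CPM so expected. The method assumes that haemoglobin in other classes comes from free RNA and that cells of all classes release RNA alike.

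The counting was tested on simulated data, with Poisson counts drawn from the profile of limb macrophage-like cells at their depths. There 95.7% of the intervals held the true ratio, 0 of 5217 unchanged genes were named, a planted 2-fold change was named in 0% of genes and a 4-fold change in 98.3%. Lists of unchanged genes fell in the outer 5% in 3.5% of cases. The simulation holds no variation between animals, so it tests counting and not differences between libraries. With 1 library per group no test between groups, no replicate spread and no paired comparison was possible. Alternatives covered doublets, resolution, components, the gene minimum, separate clustering, scaling, weighting of cells, the choice of feature, haemoglobin in the totals, count minimums, thinning depth and, added later, free RNA and HMGB2. Connective tissue-like, endothelial-like and skeletal muscle-like cells were too few at day 1 and were not compared within the class. Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.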

Results

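Blood leukocytes, blood leukocytes collected together with presumptive peritoneal macrophages, and amputated limb tissue 1 day and 6 days after amputation were profiled as single cells in adult female axolotls, with 1 library per group. After filtering, 7739 cells of the blood library, 4828 of the library with peritoneal cells, 8238 of the day 1 limb and 9736 of the day 6 limb were compared. The median depth of these cells was 3552 UMIs in blood, 13673.5 with peritoneal cells, 4238.5 at day 1 and 4035 at day 6. With 1 library per group no test between groups is possible, so that values stand as higher or lower and intervals cover counting error alone. Tissue state, animal and preparation cannot be separated between any 2 libraries. Genes are transcript contigs summed by symbol, and the class names below (macrophage-like and so on) come from marker lists.

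Blood leukocytes alone were mostly thrombocyte-like, while the library with peritoneal cells was rich in macrophage-like cells. Thrombocyte-like cells, nucleated cells that serve clotting in amphibians, made up 55.5% [54.4, 56.6] of the blood library and 9.22% [8.42, 10.1] with peritoneal cells. Macrophage-like cells took 1.01% [0.797, 1.26] and 20.8% [19.6, 21.9]. A further low-UMI cluster with macrophage markers, left without a class, held 0.207% and 10.3%. T-like cells took 9.60% [8.95, 10.3] and 15.5% [14.5, 16.6], neutrophil-like cells 6.90% [6.35, 7.49] and 8.29% [7.52, 9.10], and erythrocyte-like cells 1.51% [1.25, 1.81] and 10.96% [10.1, 11.9]. Clusters led by IGJ, the joining chain of secreted antibody, and CLEC17A, a lectin receptor of B cells, had 17.8% and 22.9%; IGJ itself was detected in 13.1% and 18.8% of these cells. A cluster led by LYZ (lysozyme) and LECT2 held 515 cells in blood and 5 with peritoneal cells. That cluster matched the macrophage list best, but no class had most markers among its leading genes, so it was left without a name. With each library clustered on its own the macrophage-like share of the blood library was 7.48%, and with doublets kept 0.394%. The thrombocyte-like share with peritoneal cells was 19.2% at the lower resolution, and the erythrocyte-like share of blood 0.387% with the stricter gene minimum. GZMB-led cells, named after a cytotoxic granule protease, took 0.672% and 1.10%.

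**Figure D1:**
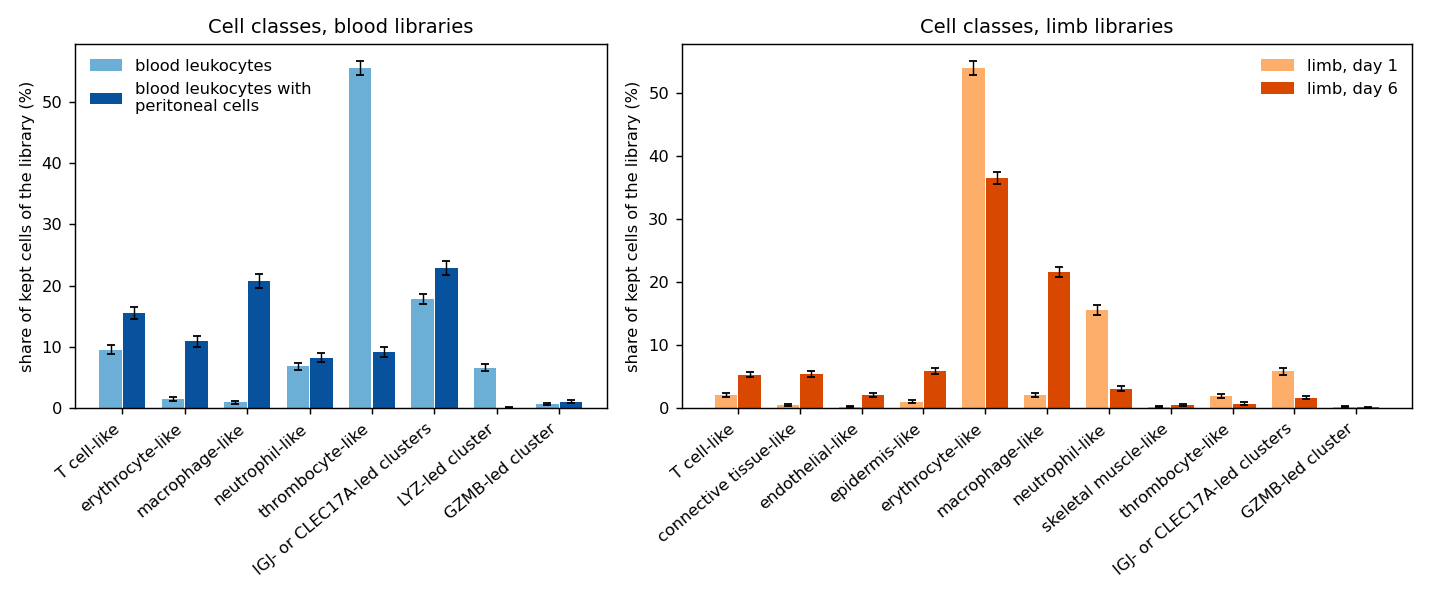
Shares of kept cells per class in the blood libraries (left) and the limb libraries (right), in percent, with exact 95% binomial intervals over cells.

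Macrophage-like cells of the library with peritoneal cells carried CR2, a receptor for complement fragments, MAS1L, a receptor of the Mas family, and the complement gene C4A, all scarce in blood. SIGLEC1, which binds sialic acid on macrophages, LTA4H, which makes leukotriene B4, and FCNB, a ficolin that recognises microbial sugars, were higher too. In the 78 macrophage-like cells of the blood library, genes of the platelet receptor for von Willebrand factor (GP9, GP1BB, GP1BA), THBS1 of platelet granules, and RHAG of red cells were higher instead, beside GPNMB, a glycoprotein of phagocytes. Named as higher with peritoneal cells were also HBB-BH1, RBPMS, CDIP1, STBD1, COLGALT1 and FMN2, and as lower CALD1, CYR61, ID3, C6ORF25 and SERPINE2; the most abundant HBB-BH1 feature alone stood at -0.03. These cells lay in clusters 17 (42 cells) and 19 (35 cells), against cluster 4 (899 cells) and 16 (92 cells) with peritoneal cells. CR2 had 3 counts in blood and 42337 with peritoneal cells (log2 ratio 8.39 [6.85, 10.67]), MAS1L 2 and 20529 (7.93 [6.08, 10.98]), and C4A 0 and 9244, at least 73.4-fold higher. SIGLEC1 differed by 4.92, from 8.33 to 252 CPM, and LTA4H by 4.91, while FCNB had a log2 ratio of 5.61 [4.06, 7.89]. On the lower side stood RHAG (-6.95), GP9 (-6.43), THBS1 (-6.14), GP1BB (-5.93) and GPNMB (-5.28, from 260.0 to 6.71 CPM). The median over all genes was -0.30. In blood, GP9 lay at 5.61 and GP1BA at 5.48 times the free RNA level, but RHAG at 34.2 and GPNMB at 415 times it. Over the genes named as lower the median was 6.82. The estimate assumes that all classes release RNA alike. Cluster 17, with RHAG among its leading genes, had a median of 1277 UMIs in blood. Carry-over from thrombocyte-like cells, or doublets with them, therefore stays open for the platelet genes. RHAG came with little haemoglobin (0.0265% of UMIs in these cells, against 36.4% in erythrocyte-like cells of blood). Its source was not tested. Matrix proteases and inhibitors had a median of -1.78 over 12 members, 2 higher and 10 lower (percentile 0 of 10000 random lists; MMP8 -4.09, PLAU -3.12). The S phase list stood at 0.41 (percentile 99.99; 14 of 21 higher, MCM2 1.84), and at 0.09 with free RNA subtracted.

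Neutrophil-like cells from the library with peritoneal cells showed an interferon pattern: GBP2 and GBP3, guanylate-binding proteins induced by interferon, and HERC5, which attaches ISG15 to proteins, were all higher. They came from cluster 7 in blood and cluster 12 with peritoneal cells. GBP2 had a log2 ratio of 4.43, GBP3 of 3.84, HERC5 of 3.85, CLEC2D, a lectin ligand of natural killer receptors, of 3.91, and MAS1L of 7.70. The 4 measured interferon-stimulated genes were all higher, with a median of 1.66 (percentile 99.96; IRF7 2.59, IRF1 2.41). Inflammatory cytokines and regulators had 6 of 10 members higher and a median of 0.70 (percentile 99.91), with SOCS1 at 3.39, CCL4 at 2.03 and IL8 at -3.30. ASS1, an enzyme of arginine synthesis, was lower (-4.48), as were COX6B1 (-4.35), GGH.26 (-3.07), ALOX12B (-2.49) and SEPW1 (-2.45).

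T-like and thrombocyte-like cells of the library with peritoneal cells held transcripts typical of its macrophage-like cells. T-like cells were in cluster 5 in blood and in clusters 9 and 13 with peritoneal cells; thrombocyte-like cells were in clusters 1 and 14, and in cluster 11. In T-like cells CR2 (8.04 [5.55, 13.34]), FABP1 (7.21 [4.72, 12.52]) and the scavenger receptor MARCO (6.30 [3.80, 11.62]) were higher from 1 count each, as was IGLL1, a light chain of immunoglobulin type (9.12 [6.64, 14.43]). IGLL1 and IGJ are both among the leading genes of cluster 13, and IGJ, a marker of antibody-secreting cells, went from 4.83 to 185 CPM in T-like cells, with UMIs in 9.08% of them. In thrombocyte-like cells CR2 (8.51), MAS1L (4.95), MARCO (4.59), C1QB of the C1q complex (4.35) and the lipid carrier APOE (4.03) were higher. In T-like cells the ratio of observed CPM to the level that free RNA would give was 1.13 for CR2, 1.55 for FABP1 and 1.10 for MARCO, but 93.3 for IGLL1 and 43.1 for LY6E. The median ratio over the genes named as higher was 1.60 in thrombocyte-like cells, against 86.4 in neutrophil-like and 27.9 in macrophage-like cells. For macrophage-like cells a high ratio was set in advance, since they gave 25203875 of the library's 62722399 UMIs. Lower in T-like cells were NLRP39 (at least 69.6-fold), ETF1 (-3.61), TRY10 (-3.13) and CTR9 (-3.04). In thrombocyte-like cells PERP (-5.38 [-10.69, -2.89]), a gene of cell adhesion, AK1 (-4.47 [-9.78, -1.98]) and SERPINB6 (-4.39 [-7.44, -2.53]) were lower, as were ST8SIA6 and TRIM38, and in T-like cells LY6E (7.11 [5.25, 10.16]) was higher. Erythrocyte-like cells had APOE (5.80 [3.32, 11.11]) and C1QB (3.89 [2.02, 6.94]) higher, with SYNDIG1, DDIT4 and MAS1L. The level of free RNA was set there from macrophage markers, APOE and C1QB among them, so it is no evidence on these. THBS1 (-3.19), MT-ND1 (-2.56), ECT2L3.1 (-1.81) and SERPINB10 (-1.74) were lower.

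At day 1 after amputation the limb held many neutrophil-like and few macrophage-like cells, and at day 6 macrophage-like cells were the largest class after erythrocyte-like cells. Macrophage-like cells took 2.19% [1.88, 2.52] at day 1 and 21.6% [20.8, 22.4] at day 6. Neutrophil-like cells took 15.5% [14.8, 16.4] and 3.14% [2.81, 3.51], and a low-UMI cluster with neutrophil markers a further 13.7% and 0.0616%. Low-UMI clusters with macrophage markers held 0.971% and 11.3%, and a low-UMI cluster with epidermis markers 0.303% and 3.90%, all left without a class. T-like cells were at 2.14% [1.84, 2.47] and 5.35% [4.91, 5.82], epidermis-like cells at 1.06% [0.847, 1.30] and 5.93% [5.47, 6.41], and connective tissue-like cells at 0.546% and 5.50%. Endothelial-like cells took 0.291% and 2.16%, skeletal muscle-like cells 0.291% and 0.472%, and thrombocyte-like cells 1.98% and 0.760%. Erythrocyte-like cells took 54.0% [52.9, 55.1] and 36.6% [35.6, 37.6]. Counted over the other cells, macrophage-like cells were 4.75% at day 1 and 34.1% at day 6, and neutrophil-like cells 33.8% and 4.96%. Clusters led by IGJ took 5.86% and 1.67%, with IGJ detected in 10.97% and 13.5% of their cells. Some shares moved by over 1.5 times with the processing. At day 6 epidermis-like cells took 9.67% and connective tissue-like cells 2.97% with separate clustering, and skeletal muscle-like cells 0.154% to 1.76%. At day 1 neutrophil-like cells took 25.4% and T-like cells 3.56% with the stricter gene minimum. The day 1 macrophage-like class is nearly all of the LYZ-led cluster 9; at the lower resolution this class held 0.0121% of day 1 cells and 17.4% of day 6 cells, and at the higher resolution 0.303% and 17.3%.

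Limb macrophage-like cells, taken as a class, held more inflammatory transcripts at day 1 and more lipid and lysosome transcripts at day 6. Most day 6 cells lay in a cluster without day 1 cells. IL8, which attracts neutrophils, the collagenase MMP1, the AP-1 member FOSL1, the redox protein TXN, WFDC17 and the interferon-induced IFITM2 were lower at day 6. FABP1 and PMP2, which bind fatty acids, were among the genes with the largest ratios, and APOE, GPNMB and TREM2, a receptor of lipid-laden macrophages, were higher. Day 1 cells came from the LYZ-led cluster 9 (179 of 180 cells). Day 6 cells came from cluster 4 (1517 cells, led by CTSLA, FABP1, APOE and GPNMB), cluster 9 (473 cells) and cluster 23 (113 cells). FABP1 had 4 counts at day 1 and 81545 at day 6 (log2 ratio 11.20 [9.84, 13.07], from 1.30 to 3054 CPM), and PMP2 went from 50.8 to 5580.1 CPM (6.78). PGBD5 (5.97 [4.42, 8.25]), BCMO1, which cleaves carotene (5.56 [3.07, 10.86]), and ATHL1 (4.95) were higher too, as were STMN3, LPAR3, ZCCHC3, STON1 and GTSF1. The collagens COL3A1 and COL1A1 were named too, at 0.608 and 0.568 of the free RNA level. WFDC17 had a ratio of -9.96 [-12.25, -8.41], IFITM2 of -7.94, IL8 of -6.29 (from 1028 to 13.2 CPM), MMP1 of -6.23 (868 to 11.5), SDS of -5.28, TXN of -4.93 and FOSL1 of -4.49, with ETS2 at -4.23; BTN1A1, CLTA, GSTM1 and CA2 were also named as lower. Several of these are transcripts of day 1 neutrophil-like cells too, where IL8, MMP1, WFDC17, BTN1A1 and IFITM2 lead cluster 6 and WFDC17 had 1013 CPM, against 112 in macrophage-like cells. The neutrophil marker CAMP moved with them in macrophage-like cells, from 106 to 50.8 CPM. The median over all genes was 0.32.

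All 11 measured inflammatory cytokines and regulators were lower in day 6 macrophage-like cells, with a median of -2.36 (percentile 0), among them TNF (-4.77), SOCS3, a brake on cytokine signalling (-3.11), and CCL4 (-3.03). Of 16 immediate early genes 14 were lower (median -1.79, percentile 0; EGR1 -3.35, EGR2 -3.21, ZFP36 -2.83). All 8 lipid handling genes were higher (1.94, percentile 100; GPNMB 2.91, TREM2 2.61, APOE 2.23, NPC1 2.13). Of 14 lysosome and phagocytosis genes 11 were higher (0.96, percentile 99.97; CTSZ 1.44, LGMN 1.38). Interferon-stimulated genes were lower in 4 of 5 (-0.71, percentile 1.96; IRF1 -1.02), and all 65 cytoplasmic ribosomal protein genes were lower (-0.58, percentile 0.01). Collagens and matrix genes were higher in 12 of 13 (2.34, percentile 100), at a median of 0.608 of the free RNA level; with free RNA subtracted the median was 0.12 over the 3 members left. The remaining lists had medians between -0.18 and 0.51. These were matrix proteases and inhibitors (-0.10, percentile 16.2, 6 of 13 higher; TIMP1 -3.72, TIMP2 2.65), glycolysis (-0.13, 13.2, 4 of 11; the glucose carrier SLC2A1 -3.59), and oxidative phosphorylation (median 0.00 to 2 decimals, 29.2, 11 of 22). Heat shock proteins stood at -0.08 (22.9, 3 of 8), S phase at 0.08 (8.45, 11 of 20), G2 and mitosis at 0.08 (20.8, 10 of 17), and MHC class II antigen presentation at -0.18 (16.0, 0 of 4). Complement stood at 0.24 (54.0, 5 of 9; ITGAM 3.13), iron and haem handling at 0.08 (35.3, 5 of 8; HPX -5.58) and secreted growth factors at 0.08 (36.2, 3 of 5; IGF2 1.91, TGFB1 -1.09). Wound keratinocyte genes stood at 0.51 (86.0, 3 of 6; -0.41 with free RNA subtracted), and oxidative burst and redox genes at -0.18 (5.88, 5 of 16; PRDX1 1.71).

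Within the LYZ-led cluster alone, which held nearly all macrophage-like cells of day 1, the inflammatory genes were again lower at day 6, while the lipid genes differed little. The median was -1.52 for inflammatory cytokines and regulators (2 of 11 higher; IL1R2 -2.04, SOCS1 -1.90) and -1.13 for immediate early genes (1 of 16; FOSL1 -3.13, ZFP36 -2.70), both at percentile 0. Lipid handling genes had a median of 0.30 (percentile 83.2; NPC1 1.11, APOE 0.59, GPNMB 0.44) and lysosome genes of 0.34 (97.92), with the median of all genes at 0.22. Ribosomal protein genes stood at -0.05 and interferon-stimulated genes at -0.02 (2 of 4 higher), so their differences in the whole class were not seen within this cluster. IL8 (-5.02), MMP1 (-5.63), IFITM2 (-7.04), WFDC17 (-9.24 [-14.55, -6.75]) and SDS, a serine-degrading enzyme (-7.55 [-12.87, -5.04]), were lower. FABP1 (6.09), COL3A1 (6.78 [4.28, 12.09]), COL1A2 (4.22 [2.63, 6.53]), TRNA (4.96) and the keratin KRT5 (4.25) were higher here. Of these all but TRNA lay under the free RNA level (FABP1 at 0.643, COL3A1 at 0.547, COL1A2 at 0.525 and KRT5 at 0.456 of it). With free RNA subtracted nothing was left of FABP1 at day 6. Its ratio then (-1.08) was set by the floor of 3 counts.

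Neutrophil-like cells of the limb likewise held inflammatory transcripts at day 1 that were scarce at day 6. WFDC17, the neutrophil collagenase MMP8, the chemokines CXCL2 and IL8, and SDC4, a heparan sulfate proteoglycan, were lower at day 6. Day 1 cells lay in clusters 6 and 15 and day 6 cells in cluster 16. MMP8 went from 4451 to 58.9 CPM (-6.24), IL8 from 3295 to 73.6 (-5.49), WFDC17 had a ratio of -8.69 [-11.74, -6.84], CXCL2 of -6.15 [-11.46, -3.67] and SDC4 of -5.55. All 16 immediate early genes were lower (median -1.56, percentile 0; FOSL1 -4.05, EGR1 -3.30), as were 10 of 13 inflammatory genes (-1.58, percentile 0; CCL4 -3.57, NFKBIA -2.63) and all 5 interferon-stimulated genes (-0.79, percentile 1.12; IRF7 -0.97). The 3 measured growth factors, AREG, EREG and TGFB1 (-0.85), were lower. S phase genes were higher in 15 of 17 (1.28, percentile 99.95; UHRF1 2.75, RPA2 2.26) and G2 and mitosis genes in 5 of 5 (1.16; BIRC5 3.51), against a median of 0.28 over all genes. With free RNA subtracted the medians were -0.87 for immediate early and 0.82 for S phase genes, and that of G2 and mitosis genes was 0.47 with the higher count minimum. FABP1 (9.18 [7.62, 11.47]), PMP2 (4.58), MARCO (4.36), KRT5 (4.31) and APOE (4.15) were named as higher, at a median of 0.804 of the free RNA level. With free RNA subtracted, nothing was left of PMP2 (-1.60) and APOE (-2.36) at day 6. Their ratios were set by the floor of 3 counts.

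T-like cells of the limb showed more cell-division transcripts at day 6 and fewer of immediate early genes. CDK1, which drives entry into mitosis, went from 2 to 88 counts, CENPF of the kinetochore from 1 to 43 and the spindle kinase TTK from 1 to 32 (16.1-fold [4.33, 135], 15.8-fold [2.68, 637] and 11.7-fold [1.96, 477] in CPM). All 15 measured G2 and mitosis genes were higher, with a median of 1.77 (percentile 100), and 19 of 20 S phase genes (0.91, percentile 97.72; RRM1 2.40), against 0.46 over all genes; with free RNA subtracted the medians were 1.58 and 0.87, and with the higher count minimum that of G2 and mitosis was 1.11. CXCR4, which guides leukocytes along CXCL12, was lower (-3.29), as were IL8 (-4.56), TIMP1 (-3.35), G0S2 (-3.03) and the light chain gene IGLL58 (-5.97). At day 1 IL8 lay at 1.24 and TIMP1 at 2.52 times the free RNA level. Of 8 immediate early genes 7 were lower (-0.68, percentile 0.01; FOSL1 -2.81, DUSP1 -1.78, JUNB -1.63). Inflammatory genes went both ways (-0.22, 4 of 8 higher), and with free RNA subtracted their median was 0.30. Both days drew on cluster 8. PMP2 (6.61), FABP2 (6.48 [3.99, 11.79]), FABP1 (6.21 [4.66, 8.49]), APOE (5.75) and C1QC (5.72 [3.86, 8.77]) were higher, at a median of 0.907 of the free RNA level.

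In epidermis-like cells genes of wound-edge keratinocytes were higher at day 1 and cell-division genes at day 6. LAMB3 and LAMA3 encode laminin chains of the matrix under keratinocytes. LAMB3 (-3.73) and LAMA3 (-3.48) were lower at day 6, as were the plasminogen activator PLAU (-3.61), MMP8 (-5.74), FOSL1 (-5.73), SLC6A14.1 (-5.54) and IL8 (-5.33). MMP8 had 13419 CPM at day 1 here (76.7 times the free RNA level), more than the 4451 CPM of neutrophil-like cells. Wound keratinocyte genes were lower in 8 of 11 (-1.44, percentile 0), and matrix proteases and inhibitors in 7 of 11 (-0.83; MMP1 -4.96, TIMP1 -4.62). The wound keratinocyte median was -0.47 with cells weighted equally and -0.46 with the higher count minimum, and the protease median -3.95 with free RNA subtracted and -3.61 with that minimum. Secreted growth factors were lower in 4 of 6 (-1.56; AREG -4.34, HBEGF -3.05, but MDK 5.03; -0.86 with cells weighted equally). Inflammatory genes stood at -1.57 and immediate early genes at -1.56 (percentiles 0.01 and 0; DUSP1 -3.93, BTG2 -2.14), the former at -0.94 with free RNA subtracted. All 19 S phase genes (1.65; RRM1 2.70) and all 15 G2 and mitosis genes (1.92; CDK1 10.7-fold [3.62, 52.5]) were higher, against a median of 0.45 over all genes. With doublets kept the G2 and mitosis median stood at 1.24. That setting adds only the 4 and 1 called doublets of the limb libraries, but clusters and names all cells anew. TGFBI, an adhesion protein of the matrix (6.00 [3.52, 11.31]), and the intelectin ITLN2 (5.52 [3.97, 7.80]) were higher, as were COL3A1 (at least 126-fold), FABP1 (at least 86.6-fold) and C1QC (5.82 [3.33, 11.13]). TGFBI and C1QC lay near the free RNA level (1.44 and 1.26 times it), and FABP1 at 2.14, COL3A1 at 6.55 and ITLN2 at 101 times it. Day 1 cells lay in clusters 19 (52 cells) and 12 (35), and day 6 cells in clusters 12 (419) and 19 (158).

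Erythrocyte-like cells of the limb showed genes of macrophages and connective tissue as higher at day 6, and thrombocyte-like cells genes of macrophages, with PMP2 and APOE in both. Erythrocyte-like cells came from clusters 2 and 3 at day 1 and cluster 1 at day 6, and thrombocyte-like cells from cluster 17. In erythrocyte-like cells FABP2 (6.92), FABP1 (6.56), PMP2 (5.91), MDK (5.59) and COL1A1 (5.39) were higher, and SLC10A6 at least 52.1-fold, with COL3A1, FCGBP, APOE, COL1A2, GPNMB and VAT1 beside them. The free RNA level was set there from macrophage markers, APOE and GPNMB among them; of the other genes the collagens COL1A1, COL3A1 and COL1A2 lay at 0.711, 0.868 and 0.918 of it, the rest at 0.776 to 1.58 times it and SLC10A6 at 16.8 times it. Lower were CSRP2 (at least 51.8-fold), TIMELESS5 (at least 27.6-fold), IFITM2 (-5.28), TXN (-4.17), IL8 (-3.88), SLC16A6, a carboxylate carrier (-3.68), and FKBP5, induced by glucocorticoids (-3.47), with WFDC17, ZMYM5, TRA2B and SKA2. At day 1 IFITM2 lay at 0.892, WFDC17 at 0.614 and IL8 at 1.15 of the free RNA level, and with free RNA subtracted IL8 stood at -1.45 and the others had no ratio. The most abundant TXN feature alone was higher (0.47). MMP1 (-3.54) stood at 1.60 with free RNA subtracted, set by the floor of 3 counts because nothing was left at day 1. In thrombocyte-like cells PMP2 (7.73 [5.85, 10.80]), APOE (3.68), PLBD1 (3.38) and CTSB (2.55) were higher, at 0.544, 0.797, 0.333 and 0.762 of the free RNA level. With free RNA subtracted nothing was left at day 6 of APOE (-1.72) and CTSB (-1.12), nor of PMP2 in erythrocyte-like cells (-0.99). These ratios were set by the floor of 3 counts. The stress phosphatase DUSP1 (-3.28), ARRDC2 (-3.95), COQ10B (-3.60), PHYHD1 (-2.94) and TREX2 (at least 9.28-fold) were lower. Immediate early genes were lower in erythrocyte-like (-0.91; JUNB -2.22) and in thrombocyte-like cells (-1.32), and inflammatory genes in both (-1.15 and -2.39). With free RNA subtracted the medians in thrombocyte-like cells were -0.70 and -1.80. Inflammatory genes in erythrocyte-like cells stood at -0.59 with free RNA subtracted and at -2.05 with the higher count minimum.

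**Figure D2:**
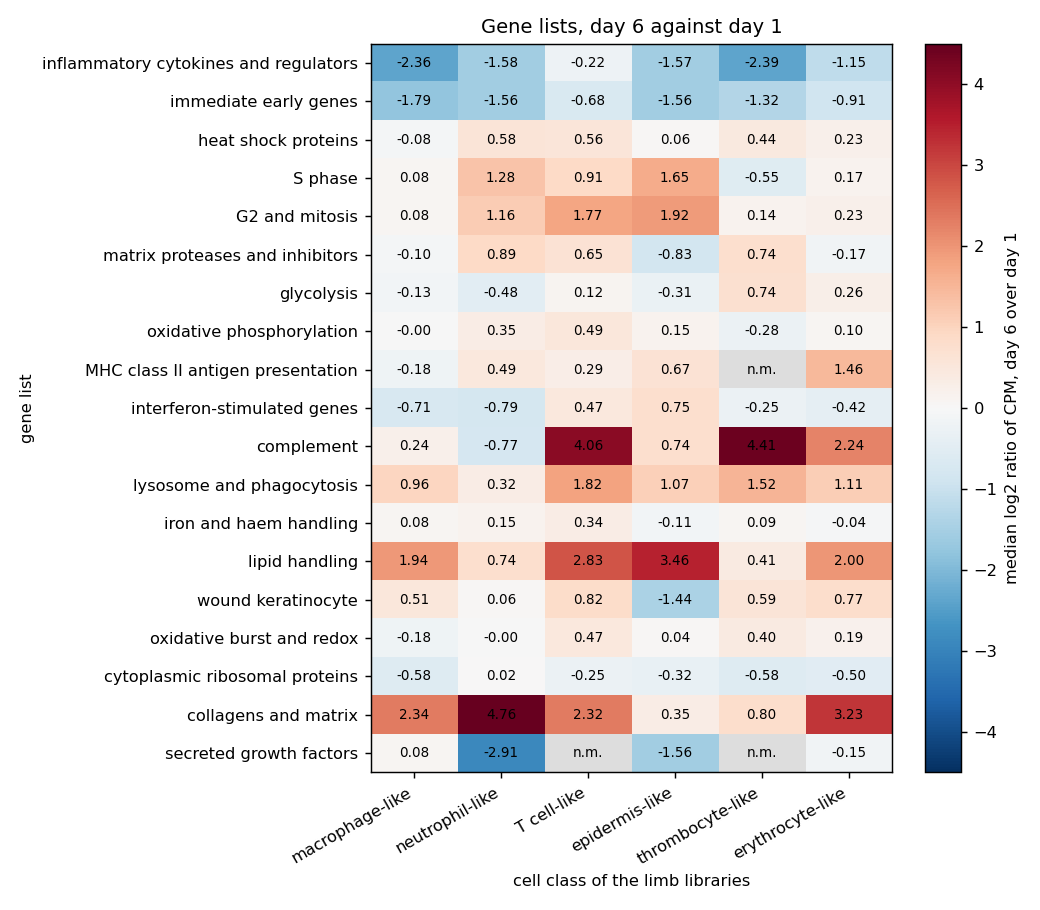
Median log2 ratio of day 6 over day 1 for each gene list in the compared limb classes; n.m., fewer than 3 measured members. Medians for macrophage and connective tissue genes outside their own classes include free RNA.

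The share of cycling limb cells was to be read from at least 2 UMIs of the G2 and mitosis list after thinning each cell to 2000 UMIs. HMGB2, a chromatin protein, gave 75.5% to 96.4% of the UMIs of this list and so filled the measure. Of macrophage-like cells 80.4% at day 1 and 74.96% at day 6 passed, and of neutrophil-like cells 95.3% and 97.9%. T-like cells were at 83.8% and 88.7%, epidermis-like cells at 72.5% and 85.6%, connective tissue-like cells at 63.6% and 89.6%, erythrocyte-like cells at 24.6% and 27.5%, and all cells at 46.8% and 56.0%. Without HMGB2, a choice made after its values were seen, epidermis-like cells passed in 5.88% [1.23, 16.2] at day 1 and 40.7% [35.8, 45.8] at day 6, and T-like cells in 5.88% [2.57, 11.3] and 17.6% [14.1, 21.6]. Connective tissue-like cells passed in 9.09% [1.12, 29.2] (2 of 22 cells) and 45.1% [39.6, 50.7]. Neutrophil-like cells had 1.59% [0.957, 2.47] and 6.44% [3.65, 10.4], and macrophage-like cells 6.70% [3.51, 11.4] and 8.59% [7.42, 9.88]. Erythrocyte-like cells had 2.17% and 2.55%.

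Across the 4 libraries, macrophage-like cells of the limb at day 6 stood out by CTSLA, a cathepsin L of the lysosome, APOE, MARCO and GPNMB. CTSLA had 1145 CPM in blood, 168 with peritoneal cells, 4504 in the day 1 limb and 24459.7 in the day 6 limb. In the same order APOE had 1699.8, 3650.4, 2204 and 10317 CPM, MARCO 93.3, 528, 585 and 2261, and FABP1 142, 706, 1.30 and 3054. C1QB differed less (up to 1522 CPM, with peritoneal cells), and LYZ was highest at day 1 (23504 CPM). The blood values come from 78 cells and leave out the unnamed LYZ-led cluster (515 cells), which had CTSLA at 263, APOE at 773 and LYZ at 19727 CPM. The LYZ-led cluster of the limb was named and gave nearly all day 1 values, so the classes compared are not alike. MMP8 and IL8, scarce in blood in both myeloid classes, were high at day 1: MMP8 at 2655 CPM in macrophage-like and 4451 in neutrophil-like cells, IL8 at 1028 and 3295. CAMP, an antimicrobial peptide of granules, marked neutrophil-like cells in all libraries (2574, 2394, 1633 and 1706 CPM, against at most 112 in macrophage-like cells).

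**Figure D3:**
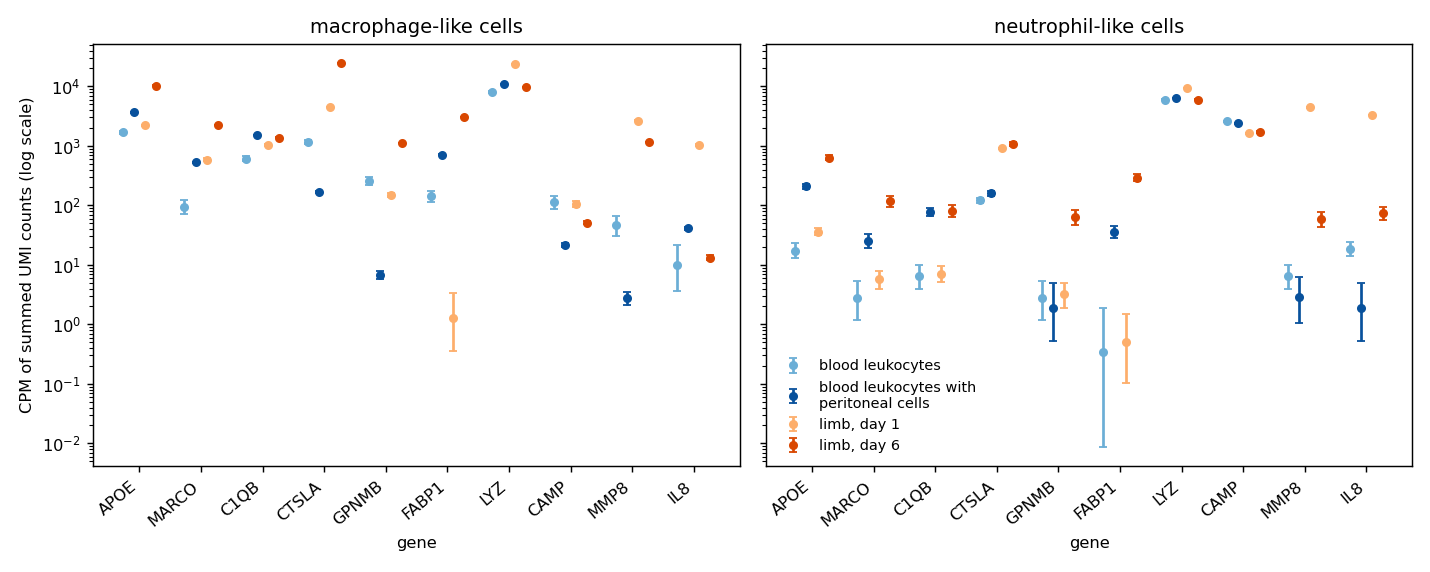
CPM of myeloid genes in macrophage-like and neutrophil-like cells of the 4 libraries, on a log scale, with exact 95% Poisson intervals of the counts.

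Neutrophil-like cells of the day 1 limb (clusters 6 and 15) held more inflammatory, immediate early and interferon-stimulated transcripts than those of blood (cluster 7). MMP8 (9.42), FOSL1 (9.35 [6.87, 14.66]) and IL8 (7.46) were higher, and the eosinophil peroxidase gene EPX (-3.08), ALOX12B (-2.94) and the transcripts MIR-150 (-2.87) and MIR-223 (-2.55) were lower, as was TRNA, and SCN1B0 was higher (7.71 [5.22, 13.01]). The haemoglobin gene HBG1 (7.55) lay at 1.04 of the free RNA level. That level was set from haemoglobin genes, HBG1 among them, so this ratio is no evidence. All 13 inflammatory genes were higher (median 3.36, percentile 100; CCL4 5.59), as were 15 of 16 immediate early genes (1.88, percentile 100; ZFP36 4.61) and all 5 interferon-stimulated genes (3.02, percentile 99.92; IRF7 4.89, IRF1 3.02). Lipid handling genes were higher in 5 of 7 (1.04, percentile 99.46), MHC class II genes in 3 of 4 (1.56, 97.53) and complement genes in 6 of 7 (0.81, 98.1; 2.40 with free RNA subtracted). The median over all genes was 0.00.

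Macrophage-like cells of the day 6 limb were set against those of the library with peritoneal cells (clusters 4 and 16 of the blood clustering). The limb cells carried more transcripts of lysosomal and lipid genes and of matrix proteases and inhibitors, and less of the complement gene C4A. MMP8 (8.72), PMP2 (8.23), PGBD5 (7.78) and GPNMB (7.39) were higher, and C4A (-9.80), RBPMS (-8.48), STBD1, which binds glycogen (-8.08), and MAS1L (-7.05) lower. RASGEF1B, HBA-L5, COL1A2, S100A10B (at least 180-fold) and PIGR were also named as higher, and TDRD9, LINGO2, LAMA5, WDR52 (at least 357-fold), SEMA3E, CYP2D62 (at least 154-fold) and SLIT3 as lower. Lysosome genes were higher in 13 of 14 (median 2.47, percentile 100; CTSB 4.14, CTSD 3.28), and all 8 lipid handling genes were higher (3.18, percentile 99.99; PLIN2 4.33, TREM2 4.08). Matrix proteases and inhibitors were higher in 11 of 12 (2.51, percentile 99.99), the inhibitor TIMP2 (6.21) among them. With free RNA subtracted their median was 3.12. All 65 ribosomal protein genes were lower (-1.42), against 0.82 over all genes. KRT5 (at least 319-fold higher) and COL3A1 (at least 283-fold) were among 6 of the 12 genes named as higher that lay under 2 times the free RNA level. So were HBA-L5, COL1A2 and S100A10B, at 0.737, 0.573 and 0.796 of it, but not RASGEF1B and PIGR (27.2 and 29.2 times it). HBA-L5 is among the haemoglobin genes that set this level, so its ratio is no evidence. Tissue, state and preparation all differ between these libraries.

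In all limb cells together, the collagenase MMP13 (7.52 [5.66, 10.57]), the collagen COL11A1 (7.46 [5.91, 9.74]) and SFRP2, a Wnt modulator (6.98), were higher at day 6, beside FABP1 (10.12). All 16 measured collagens and matrix genes were higher (median 3.23, percentile 100), while matrix proteases and inhibitors went both ways (-0.56, 7 of 15 higher). DIO3 (at least 629-fold), BCMO1, LEAP2, C1QL2, MAMDC2, SLC6A13, MXRA5 and FMN2 were also named as higher. IL8 (-5.47), TNF (-4.36) and CDKN1A, a brake on the cell cycle (-5.21), were lower, with CSRP2, IGLL58, IFITM2, PPP1R3C.1, NRGNA, TIMELESS5, SPIB and DHRS9. Of the limb patterning and blastema list 4 genes could be measured, in all cells only: HOXD11 (23.8-fold [6.33, 201], from 2 counts), LHX2 (4.26-fold [1.24, 22.6], from 3 counts), KAZALD1 (2.49) and SALL4 (1.25), with a median of 2.29 (percentile 98.1). The median over all genes was 1.01. Sums over all cells follow the shares of the classes: erythrocyte-like and neutrophil-like cells had lower shares at day 6, and connective tissue-like (0.546% and 5.50%) and macrophage-like cells higher ones. In all blood cells CR2 (7.86), C4A (9.22), FABP1 (7.31) and MAS1L (7.21) were higher with peritoneal cells, with VILL, CA10, LINGO2, RBPMS, EPPK1, CYP2D62, PTN and CMTM5, and SPARC, a matrix protein of platelets (-6.50), PERP (-5.54), SERPINB12 (-6.05) and CDH5 (-4.57) were lower, with NLRP39, SERPINB2, MYCN, SULT6B1, FHOD3, CLIC2 and PLVAP.

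**Figure D4:**
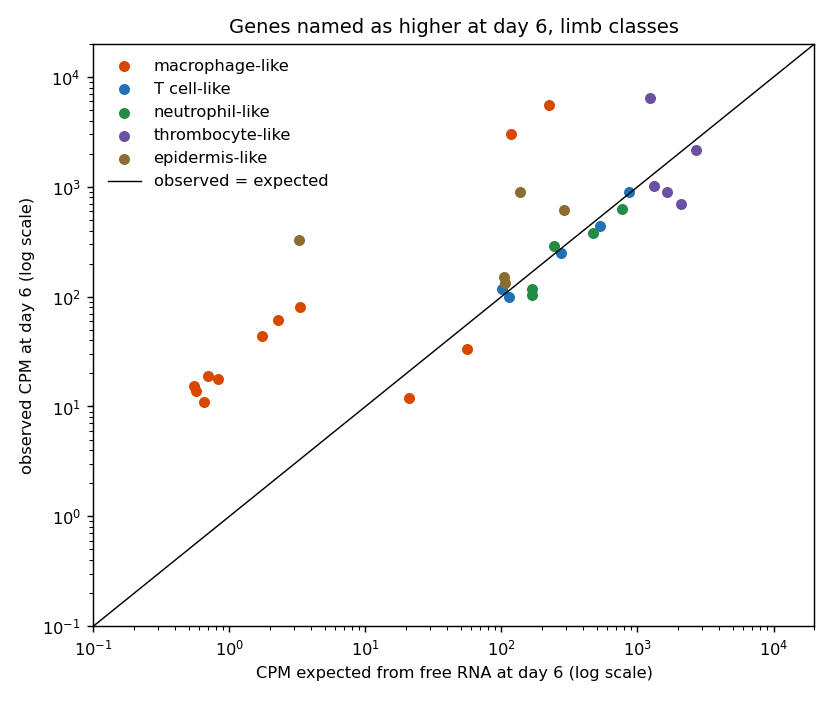
Observed CPM at day 6 against the CPM expected from free RNA, for the genes named as higher at day 6 in 5 limb classes. Points on the diagonal are at the level of free RNA.

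Haemoglobin made up 25.5% of all UMIs at day 1 and 14.7% at day 6, and 0.278% and 1.19% in the blood libraries. From the haemoglobin UMIs in other classes, free RNA was estimated at 5.98% and 7.10% of the UMIs of limb macrophage-like cells and 8.31% and 14.8% in neutrophil-like cells. It was 14.8% and 16.7% in T-like, 16.5% and 17.5% in epidermis-like and 32.2% and 51.8% in thrombocyte-like cells. The lipid handling genes of day 6 macrophage-like cells lay at a median of 27.7 times the free RNA level. That ratio was bound to be high, because the list holds markers that named this class. Connective tissue-like, endothelial-like and skeletal muscle-like cells had 45, 24 and 24 cells at day 1, too few for a comparison between days within the class.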

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

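The tests below were chosen only after the results were seen. Median-of-ratios scaling and the higher count minimum, used in some of them, were settings fixed before the data were examined. For the free RNA tests of the blood classes as one set and of the immediate early genes in macrophage-like cells, the expected outcomes were written before these values were seen.

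Genes of macrophage-like cells, such as FABP1, PMP2, APOE and MARCO, are named as higher in T-like, neutrophil-like and thrombocyte-like cells in the libraries rich in macrophage-like cells. In the limb, observed CPM of the genes named as higher in these classes was a median of 0.823 of that expected from free RNA (quartiles 0.730 and 0.975, 15 genes, of which 14 lay under 2 times it), and in blood T-like and thrombocyte-like cells 1.57 (quartiles 1.34 and 1.63, 10 genes), so a candidate explanation for the macrophage genes there is free RNA. IGLL1 and LY6E of the blood T-like cells, at 93.3 and 43.1 times that level, are not explained so. Blood neutrophil-like cells differ, with 86.4 (quartiles 53.2 and 104, 5 genes), which argues against free RNA for these genes only. They are MAS1L, GBP2, CLEC2D, HERC5 and GBP3, of which only MAS1L (7.42) was also named in macrophage-like cells. APOE (17.4 to 209 CPM), MARCO (2.73 to 25.2) and FABP1 (0.341 to 36.2) were higher there too with peritoneal cells. They were not among the named genes, and their ratio to free RNA was not computed in this class. The lipid handling genes of day 6 macrophage-like cells lay at 27.7 (quartiles 26.9 and 28.0, 8 genes). That list holds markers that named the class, and the class gave 26699679 of the 58116919 UMIs from which the free RNA profile was taken. A high ratio was thus set in advance, so it cannot decide on free RNA there. Over the blood T-like, neutrophil-like and thrombocyte-like cells as one set the median of 1.63 (quartiles 1.55 and 69.8) is under 2 but the upper quartile is not, so for the set as a whole free RNA and expression cannot be told apart. Low expression of these genes in single cells of the other classes, or doublets of them with macrophages, stays open beside free RNA.

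Immediate early and inflammatory genes were lower at day 6 in the limb, from macrophage-like and neutrophil-like to epidermis-like cells. With median-of-ratios scaling the median of the immediate early genes in macrophage-like cells was -2.01, and with free RNA subtracted -1.81 (SD of random lists 0.191). Neither setting thus made the difference in these cells smaller than reported above. In neutrophil-like and thrombocyte-like cells the difference was smaller with free RNA subtracted, though still negative. The median was negative in 100% of the 6 compared classes, which a difference in the handling of the tissue between the 2 days could also give. With 1 library per day, handling, animal and day after amputation cannot be told apart. A course of inflammation that subsides between the days stays open as the biological explanation and was not tested.

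Limb clusters 7 and 13 hold macrophage markers at low depth, with medians of 917 and 1177 UMIs at day 6 against 12722 in macrophage-like cells. Their haemoglobin shares of UMIs were 4.44% and 6.64%, against 1.04% in macrophage-like cells and 14.7% in all day 6 cells (0.303 and 0.453 of the latter). This argues against droplets with free RNA alone only if free RNA has the profile of all kept cells. That could not be checked, since barcodes without cells were not used. In cluster 13 (437 cells) mitochondrial genes took 12.3 times the share seen in macrophage-like cells (36.1% against 2.93%), so these may be damaged cells. In cluster 7 (665 cells) the ratio was 1.27, which argues against the same reading there. Small or poorly captured macrophages remain possible for cluster 7, and no biological explanation was tested.

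Some lists had opposite directions in limb classes between day 1 and day 6, and these differences between classes were not tested. The median of matrix proteases and inhibitors was 0.89 in neutrophil-like and -0.83 in epidermis-like cells; with free RNA subtracted it was -0.55 and -3.95. That of complement genes was 2.24 in erythrocyte-like and -0.77 in neutrophil-like cells, the latter 1.92 with the higher count minimum. In erythrocyte-like cells its members lay at a median of 1.01 times the free RNA level, which was set from macrophage markers, C1q genes among them, so that value is no evidence. That of wound keratinocyte genes was 0.77 in erythrocyte-like cells, where it was -0.14 with free RNA subtracted, and -1.44 in epidermis-like cells.

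Contigs without a gene symbol, which no comparison above uses, also differed in limb macrophage-like cells. AC_02200012952.1 had 99.6 CPM and AC_02200028850.1 121 CPM at day 6 (log2 ratios 6.67, from 3 counts [34.9- to 495-fold], and 6.53). At day 1 AC_02200038898.1 had 627 CPM and AC_02200033126.2 107 CPM, each with 1 count at day 6 (3002- to 661797-fold and 509.6- to 113271-fold lower by the counting interval). What they encode is not given in the sources used here.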

How the results depend on the processing

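The tests with free RNA subtracted, with the highest doublet scores left out, with clusters holding markers of another class kept, and without HMGB2 were chosen only after the results were seen; the other alternatives, the classes' marker lists, the gene lists and the rule for named genes were fixed before the data were examined. No paired analysis was possible because no label links a sample of one library to a sample of another. With 1 library per group, the alternatives show the effect of processing and not of variation between animals. A value counts as moved when it leaves the 95% counting interval of the value reported, or, for a list, the SD of random lists. For all values below that moved or reversed, the cause was not tested, except where fewer counted genes or UMIs bring the change by construction. Depth limits the small classes: the 78 macrophage-like cells of blood, the 87 epidermis-like cells of day 1 and the 74 thrombocyte-like cells of day 6. No alternative was left out for time. Skeletal muscle-like cells got no value with fewer components, with the stricter gene minimum and, at day 1, with separate clustering, and lists with fewer than 3 members at the higher count minimum got none.

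Shares of cells follow, in percent of kept cells. With each library clustered on its own, in blood they were T 10.5%, macrophage 7.48% and thrombocyte 53.3%, and in blood with peritoneal cells they were macrophage 18.3%. At day 1 they were T 1.80%, epidermis 1.43% and erythrocyte 50.7%, and at day 6 they were T 6.77%, connective tissue 2.97%, epidermis 9.67%, erythrocyte 35.0%, macrophage 23.6% and skeletal muscle 1.76%. With the stricter gene minimum, in blood they were T 10.7%, erythrocyte 0.387%, macrophage 1.75% and thrombocyte 53.5%, and in blood with peritoneal cells they were T 13.5%, macrophage 25.01% and neutrophil 9.46%. At day 1 they were T 3.56%, erythrocyte 55.8%, macrophage 3.03% and neutrophil 25.4%, and at day 6 they were T 7.32%, endothelial 1.83%, epidermis 8.79%, erythrocyte 34.9%, macrophage 31.2% and neutrophil 3.76%. At the lower resolution, in blood they were macrophage 0.788%, and in blood with peritoneal cells they were macrophage 18.7% and thrombocyte 19.2%. At day 1 they were T 2.97%, epidermis 1.34% and macrophage 0.0121%, and at day 6 they were T 6.13%, epidermis 9.39%, erythrocyte 37.6%, macrophage 17.4% and skeletal muscle 0.154%. At the higher resolution, in blood they were macrophage 1.81% and thrombocyte 53.1%, and in blood with peritoneal cells they were T 11.4%. At day 1 they were macrophage 0.303%, and at day 6 they were macrophage 17.3%. With fewer components, in blood they were thrombocyte 53.1%, and in blood with peritoneal cells they were T 10.6%. At day 1 they were T 3.01% and epidermis 0.728%, and at day 6 they were T 6.50%. With doublets kept, in blood they were macrophage 0.394% and neutrophil 7.70%, and at day 1 they were epidermis 1.38%. At day 6 they were epidermis 9.60% and macrophage 22.7%. In the limb this setting adds only the 4 and 1 called doublets, too few to give these moves, and all cells were clustered and named anew. With the highest doublet scores left out, in blood they were thrombocyte 54.3%, and in blood with peritoneal cells they were T 11.3%. At day 1 they were T 1.78%, and at day 6 they were T 4.79%, erythrocyte 39.0%, macrophage 23.2% and skeletal muscle 0.167%. With clusters holding markers of another class kept, at day 1 they were T 2.96%, and at day 6 they were T 6.14%. In all these settings that gave values, macrophage-like cells had a higher share with peritoneal cells than in blood and at day 6 than at day 1, and neutrophil-like cells had a lower share at day 6. At the lower and higher resolution the day 1 macrophage-like class held only 0.0121% and 0.303%, against 2.19% reported. There the direction depends on which clusters kept the name, so it adds little.

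For named genes, the ratio left its interval for 26 of 244 with doublets kept, 5 with haemoglobin left out of totals, 38 with cells weighted equally, 40 with median-of-ratios scaling and 21 with the most abundant feature per symbol. With that feature alone the direction reversed: HBB-BH1 stood at -0.035 in blood macrophage-like cells and TXN stood at 0.47 in limb erythrocyte-like cells. With free RNA subtracted, APOE stood at -0.51 in blood erythrocyte-like cells, PMP2 stood at -0.99 in limb erythrocyte-like cells and MMP1 stood at 1.60 in limb erythrocyte-like cells. PMP2 stood at -1.60 in limb neutrophil-like cells, APOE stood at -2.36 in limb neutrophil-like cells and APOE stood at -1.72 in limb thrombocyte-like cells. CTSB stood at -1.12 in limb thrombocyte-like cells and FABP1 stood at -1.08 in limb LYZ-led macrophage-like cells. These 8 reversed with free RNA subtracted, but in each a subtracted count stood at the floor of 3 in one library. They therefore show no measured reversal. A further 46 of 196 moved, 116 did not, and 26 had no ratio left because both counts fell to the floor. In erythrocyte-like cells the amount of free RNA was set from macrophage markers, so the values of such markers there, APOE among them, are no evidence. With the lower count minimum, the genes first by rank included 2 of the 10 named in limb thrombocyte-like and 3 of 10 in blood neutrophil-like cells. They included 5 of 10 in blood erythrocyte-like cells, in the LYZ-led cluster alone and in neutrophil-like cells between day 1 limb and blood. In blood T-like and thrombocyte-like and limb epidermis-like and neutrophil-like cells it was 6 of 10, and in limb T-like cells 7 of 10. Of 24 named, it was 12 in limb erythrocyte-like, 17 in blood and 19 in limb macrophage-like cells, 18 in all limb and 19 in all blood cells, and 24 in macrophage-like cells between day 6 limb and peritoneal cells. In the myeloid panel 20 of 80 values moved with doublets kept and 39 with cells weighted equally.

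For gene lists in limb classes, medians moved with median-of-ratios scaling: the inflammatory list stood at -0.59 in T, -1.43 in erythrocyte and -2.01 in neutrophil and the immediate early list stood at -1.06 in T, -1.19 in erythrocyte, -2.01 in macrophage, -1.99 in neutrophil and -1.67 in thrombocyte. The lysosome list stood at 1.45 in T, 0.82 in erythrocyte, 0.74 in macrophage, -0.11 in neutrophil and 1.17 in thrombocyte and the lipid list stood at 2.46 in T and 0.31 in neutrophil. With free RNA subtracted, the inflammatory list stood at 0.30 in T, -0.94 in epidermis, -0.59 in erythrocyte and -1.80 in thrombocyte and the immediate early list stood at -0.87 in neutrophil and -0.70 in thrombocyte. The lysosome list stood at 0.44 in T, 0.73 in epidermis, 0.042 in erythrocyte, -0.073 in neutrophil and 0.25 in thrombocyte and the lipid list stood at 0.43 in T, 0.75 in epidermis, -0.76 in erythrocyte, -0.82 in neutrophil and -0.92 in thrombocyte. The matrix protease list stood at -0.55 in neutrophil and the wound keratinocyte list stood at -0.14 in erythrocyte. In this setting the inflammatory list in T-like cells, the lipid and wound keratinocyte lists in erythrocyte-like cells and the matrix protease list in neutrophil-like cells reversed. A list counts as reversed only where its reported median was in the outer 5% of random lists. Outside these, the wound keratinocyte list in macrophage-like cells (-0.41), the lysosome and lipid lists in neutrophil-like and the lipid list in thrombocyte-like cells changed sign by more than the SD of random lists. So did the heat shock, S phase, matrix protease, oxidative phosphorylation and redox lists in erythrocyte-like cells and the wound keratinocyte list in neutrophil-like cells. The matrix protease list in epidermis-like cells moved to -3.95 and the S phase list in neutrophil-like cells to 0.82. The lipid, lysosome and complement lists hold macrophage markers, so their values in erythrocyte-like cells are no evidence. With the higher count minimum, the inflammatory list stood at -0.55 in T, -1.99 in epidermis and -2.05 in erythrocyte and the immediate early list stood at -1.77 in neutrophil. The lysosome list stood at 0.78 in thrombocyte and the lipid list stood at 4.34 in T and 0.00095 in neutrophil. The matrix protease list stood at -0.92 in neutrophil and the complement list stood at 1.92 in neutrophil. Here the matrix protease and complement lists in neutrophil-like cells reversed. With cells weighted equally, the inflammatory list stood at -0.86 in erythrocyte and -1.26 in neutrophil and the immediate early list stood at -1.07 in epidermis, -0.65 in erythrocyte and -1.91 in thrombocyte. The lysosome list stood at 1.39 in T and 1.86 in thrombocyte. With the most abundant feature per symbol, the inflammatory list stood at -1.49 in erythrocyte, -2.88 in macrophage and -1.88 in thrombocyte and the lipid list stood at 2.29 in T, 2.69 in epidermis and 1.49 in thrombocyte. Immediate early genes had a negative median in all 6 compared classes under each of these settings. Lists in blood classes and between tissues were recomputed with free RNA subtracted only.

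Shares of cycling cells depend on the measure, here at day 1 and day 6. Without HMGB2 they were T 5.88% and 17.6%, macrophage 6.70% and 8.59%, neutrophil 1.59% and 6.44% and epidermis 5.88% and 40.7%. The others were connective tissue 9.09% and 45.1%, erythrocyte 2.17% and 2.55% and all 2.79% and 10.3%. With shallower thinning they were T 47.5% and 65.5%, macrophage 51.1% and 44.8%, neutrophil 73.1% and 75.1% and epidermis 45.5% and 63.5%. The others were connective tissue 72.9% (day 6), erythrocyte 8.53% and 10.0% and all 29.0% and 35.4%. With no thinning they were T 92.5% (day 6), macrophage 98.9% and 98.4%, neutrophil 97.3% and 88.6% and erythrocyte 59.1% and 56.9%. The others were all 68.3% and 72.2%. With at least 1 UMI they were T 94.9% and 96.7%, macrophage 93.3% and 92.1%, neutrophil 99.2% and 99.6% and epidermis 88.2% and 94.8%. The others were connective tissue 86.4% and 96.6%, erythrocyte 58.4% and 61.5% and all 71.6% and 79.8%. With at least 3 UMIs they were T 65.4% and 77.9%, macrophage 59.8% and 54.2%, neutrophil 87.2% and 91.0% and epidermis 52.9% and 74.5%. The others were connective tissue 82.2% (day 6), erythrocyte 8.20% and 10.4% and all 32.2% and 39.3%.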

Other observations

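No tests were run on the values in this part, all of which were chosen after the results were seen.

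Several classes of limb tissue were too few at day 1 to compare within the class, but formed clusters of their own. Connective tissue-like cells lay in cluster 10 (472 cells at day 6, 26 at day 1), led by COL1A1, COL1A2, COL3A1 and THBS2, and in cluster 24 (63 and 19 cells), led by PTX3, a soluble pattern recognition protein, SFRP2, LUM, DCN and DIO3, which inactivates thyroid hormone. Endothelial-like cells (210 and 24) carried VWF, CD34 and PLVAP, a protein of vessel pores. Their 10 leading genes also held KRT8 and KRT18, so that 2 were endothelial and 2 epidermis markers of the lists. Skeletal muscle-like cells (46 and 24) carried MYLPF, ACTA1A and CKM of the contractile apparatus. Epidermis-like cells split into cluster 12, led by KRT5, S100A10B and TGM3, and cluster 19, led by KRT75, KRT17, EPCAM and CLDN4, with COL1A2 and COL1A1 of connective tissue among its 10 leading genes.

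Macrophage-like cells at day 6 included cluster 23 with 113 cells, led by HMGN2, RRM2.1, KPNA2 and SLBP, genes of DNA synthesis and nuclear import. A cluster left without a class, 26, had 59 cells at day 6 and 2 at day 1 (0.606% and 0.0243%) and was led by CTSK, the cathepsin of bone resorption, MMP2 and CKB. In blood, cells led by IGJ and IGLL5 (cluster 2, 1375 cells) came from the blood library and those led by BLK and CLEC17A (cluster 3, 1103 cells) from the library with peritoneal cells. Cluster 18, led by SFTPB, ART5 and the perforin-type gene PRF1.1, held 0.116% and 0.849% of the libraries.

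The matrix of the library with peritoneal cells holds 4988 barcodes, 10 fewer than the 4998 that the series text states, while the other counts match. HMGB2 gave 75.5% to 96.4% of the UMIs of the G2 and mitosis list, and the planned share of cycling cells is near 100% in neutrophil-like cells.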
